A study of Mus musculus with 2 samples.

How the data were processed

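Total RNA of mouse bone marrow-derived mast cells was measured on 2 Agilent one-colour (Cy3) arrays, 1 for a control siRNA and 1 for a GATA1 siRNA, each used at 200 pmol. Per the labels' protocols, marrow mononuclear cells were grown for 2 weeks with 10 ng/mL interleukin 3 and for 2 more weeks with interleukin 3 and 10 ng/mL stem cell factor, RNA was extracted with NucleoSpin RNA II columns, and 100 ng was amplified and labelled with the Low Input Quick Amp kit. The series design states that samples from 2 animals were pooled for each siRNA. Groups were taken from the transfection label of each sample. Per the file headers, both arrays lie on the same slide at 2 positions.

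Spot signals are intensity values in scanner units that the authors obtained with Agilent Feature Extraction 10.7.3.1 (1-colour gene expression protocol), per the file headers. Per the file headers, the processed signal is background-subtracted, detrended across the array surface and multiplicatively detrended, with dim spots replaced by surrogate values, and no scaling between arrays was applied. The authors also deposited a table of normalized intensity, whose columns equal each array's processed signal divided by the array's own median over its 59305 non-control spots, found by matching the values. Its median is 1 on both arrays. How that table was made is not stated, and it served here as an alternative scaling.

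Control spots and spots that the scanner software marks as outliers on either array (117 on the control siRNA array and 133 on the GATA1 siRNA array) were left out. Repeated spots of a probe were averaged on the log2 scale. Of the probes on the array, 55249 are printed a single time, 33 are printed 2 times and 399 are printed 10 times, and 55659 probes remained. Each array was divided by the 75th percentile of its probes, 303.2 for the control siRNA array and 340.0 for the GATA1 siRNA array. A probe was measured where the software calls it well above background and not saturated on both arrays. Of the probes, 29335 (52.7%) were well above background on the control siRNA array and 30709 (55.2%) on the GATA1 siRNA array. A gene's value is the mean over its measured probes. Of all genes, 20524 were measured, 12996 were not well above background on either array, 1131 and 334 were above it on the GATA1 siRNA or the control siRNA array only, and 25 had probes above background on different arrays. A gene above background on 1 array only has a bound, not a difference. Probes were named by accession (27235 probes) or symbol (3581 probes) from a RefSeq table for assembly GRCm38.p6, used for names only, and 24865 probes kept the name in the array annotation. Coordinates are those of the array annotation (mm9).

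Because each group is 1 array, no test across arrays was possible, and a rule of size (2-fold) replaced it. A fixed list of genes was described by its median difference and the percentile of that median among 10000 random lists of the same size, matched on mean level in 20 bins. A list counts as outside where the percentile leaves the central 95%. Lists needed at least 5 measured genes, and all 29 had them. The lists cover mast cell granule proteins, surface receptors, IgE receptor signalling, haematopoietic transcription factors, haem and iron, progenitors, other blood and stromal cell types, cytokines, eicosanoid enzymes, interferon-stimulated genes, DNA replication, mitosis, p53 and apoptosis, stress responses, immediate early genes, cholesterol, hypoxia, ribosomal proteins, oxidative phosphorylation and reference genes. The lists, the rule for named genes, the 2-fold rule and the alternatives were fixed before the data were examined, except for those named here as added later.

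The genes named in the text are 13 genes chosen in advance (Gata1 and other mast cell genes) and the 10 highest and 10 lowest differences among named genes. The latter must have a mean level at or above the 25th percentile of measured genes and all probes of the same sign. They further include the 5 highest bounds in each direction, the 4 members with the largest absolute difference in each list outside the central 95%, and the largest member of each other list. Unnamed models were left out of the rankings. Ctsd, Hba-a2, Hdac6, Suv39h1, Was, Pcsk1n, Glod5, Morrbid, Dgki, Ahr, Mcpt8, Prss34, the other genes listed for a cell type in the closing section and the genes that enter the rankings without marked spots were chosen after their values were seen. Of the genes in the ranking without marked spots, 1 is not reported here.

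Alternatives were another background correction (normexp with offset 50, limma 3.58.1 in R 4.3.3), and scaling to the median of measured probes, by quantiles, by loess of the difference on mean level (span 0.4) and by the authors' table. The filter on dim probes was dropped or made stricter, several probes of a gene were replaced by the brightest or by their median, outlier spots were kept, size rules of 1.5-fold and 3-fold were tried, and random lists were drawn without matching. A pair of alternatives was added after the data were seen: leaving out spots with at least 2 neighbours (up to 2 rows and 1 column away) that differ 4-fold, and random lists of named genes matched on level and on the GC content of the probes in 5 bins.

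The calculation was tested on simulated arrays with 20524 genes, 200 of them changed. The only noise in them is the SD between repeated spots. Marks on the array surface and differences between cultures or animals are absent. The counts that follow therefore do not give the rate of false calls in the real arrays. The 2-fold rule called 0 of 50 genes changed 1.5-fold, 47 of 50 changed 2.5-fold, 50 of 50 changed 4-fold, 50 of 50 changed 8-fold and 0 of 20294 unchanged genes. A list of 30 genes shifted by 0.3 had a median of 0.29 and percentile 100, and 5 of 100 unshifted lists lay outside the central 95%. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.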

Results

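RNA of cultured mouse mast cells was profiled on 2 one-colour Agilent arrays. Of these, 1 carried RNA of cells given a control siRNA and 1 carried RNA of cells given an siRNA against GATA1, a zinc finger transcription factor of erythroid, megakaryocytic, eosinophil and mast cells. The cells were grown from C57BL/6 marrow for 2 weeks in interleukin 3 and then for 2 weeks in interleukin 3 with stem cell factor, growth factors under which mast cells expand. Samples from 2 animals were pooled for each array. Of the 59305 spots with gene probes on each array, 31617 (53.3%) were well above background on the control siRNA array and 33062 (55.7%) on the GATA1 siRNA array, and no spot was saturated. In all, 20524 genes were measured on both arrays. Values are log2 differences, GATA1 siRNA minus control siRNA, of signals divided by each array's 75th percentile. With 1 array per group, no difference has a replicate check, no p-value is given, and the number of arrays limits the precision of every value.

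The comparison asks which transcripts of cultured mast cells differ when GATA1 is knocked down. Gata1 itself was 4.68-fold lower in the GATA1 siRNA array (log2 difference -2.23), and it was the second lowest among the named genes ranked by their difference. Its signal was 16415 in the control siRNA array and 3930 in the GATA1 siRNA array, and the scanner software's own error for this difference was 0.20. The transcripts that define a mast cell differed little: Kit, the receptor for stem cell factor, by 0.03, and the IgE receptor chains Fcer1a by -0.17 and Ms4a2 by 0.01. Several serine proteases of the mast cell granule were lower, with Tpsab1 at -2.11, Tpsg1 at -1.11, Mcpt4 at -0.88 and Tpsb2 at -0.55. Tpsab1 rests on 1 probe, whose signals of 623 (control siRNA) and 162 (GATA1 siRNA) were far under those of Tpsg1 (126139 and 65381). Genes of neutrophils were higher as a group, with a median difference of 0.53 over 26 measured genes, and genes of eosinophils were lower, with a median of -0.17 over 15.

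The probe for Gata1 lies on the minus strand of chromosome X at 7536392 to 7536451 (mouse genome build mm9, as the array annotation gives it). It is the only probe for the gene, and the part of the transcript targeted by the siRNA is not stated. Gata2, the related factor of progenitors and mast cells, differed by -0.05, and Gata3, a factor of T cells and type 2 responses, by -0.07. Mitf, a transcription factor that mast cells need, differed by 0.01. Cpa3, the granule carboxypeptidase, differed by 0.04, and Hdc, the enzyme that makes histamine, by -0.07, although the Hdc probe sits at a marked spot of the array surface (described further on). The signs of Gata2, Kit, Mitf and Ms4a2 depend on how the arrays are scaled: under other scalings Gata2 reached 0.02, Kit -0.01, Mitf -0.05 and Ms4a2 -0.05. Il1rl1, the interleukin 33 receptor, was lower at -0.32 over 3 probes, and Cma1, the chymase of connective tissue mast cells, differed by -0.12.

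**Figure D1:**
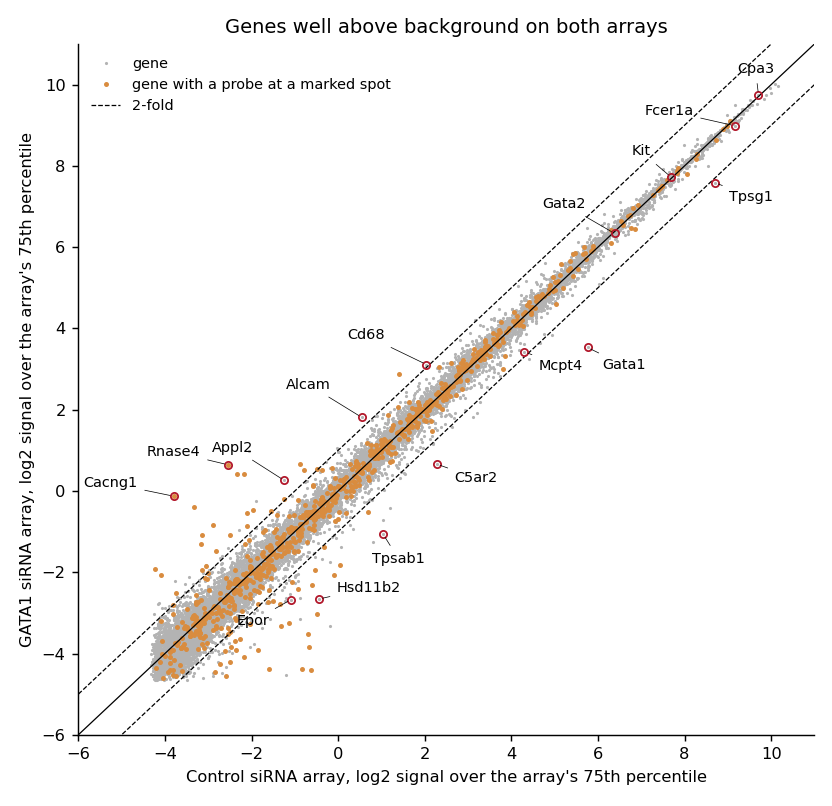
Signal of each gene measured on both arrays (log2 of the signal over the array's 75th percentile), control siRNA on the horizontal axis and GATA1 siRNA on the vertical axis, with dashed lines at a 2-fold difference and orange points for genes with a probe at a marked spot. Gata1, at a difference of -2.23, lies well under the lower dashed line, and Kit, Cpa3, Gata2 and Fcer1a lie near the diagonal.

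Most genes had similar signals on both arrays. The median difference over all 20524 genes was 0.01 with an SD of 0.29, 95.4% of genes lay within 1.5-fold and 99.1% within 2-fold, and Pearson's r across genes, which are not independent replicates, was 0.996. By the 2-fold rule 60 genes were higher in the GATA1 siRNA array and 125 were lower, so 32.4% of the genes past the rule were higher. This split moves with the scaling: with an intensity-dependent loess it was 80 higher and 108 lower (42.6% higher), and with the authors' scaling 78 higher and 105 lower (42.6% higher). Named genes made up 42 of the 60 and 74 of the 125, noncoding loci 7 and 19, and unnamed gene models 11 and 32. A further 1131 genes were well above background in the GATA1 siRNA array only and 334 in the control siRNA array only. These counts rest on detection calls, which more probes passed on the GATA1 siRNA array (55.2% against 52.7%). An unnamed probe called there only had a lower scaled signal there (-4.62) than on the control siRNA array (-4.36). The split is therefore not a count of genes that came on or went off.

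The named genes with the lowest differences were Mfsd9 at -2.83, Gata1, Hsd11b2 at -2.22, Tpsab1, Olfr224 at -1.76, Slit2 at -1.74, C5ar2 at -1.61, Epor at -1.58, Slc4a11 at -1.56 and Cited1 at -1.46. Hsd11b2 inactivates glucocorticoids, Slit2 is a secreted guidance protein, and C5ar2 is a receptor for the complement fragment C5a. Epor, the erythropoietin receptor, is a classic GATA1 target, and Cited1 is a transcriptional coactivator. The 2 probes of C5ar2 gave -1.62 and -1.61. Only the Mfsd9 probe among these sits at a marked spot, and with such spots left out the pseudogene Speer5-ps1 (-1.41) takes its place.

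The named genes with the highest differences were Cacng1 at 3.67, Rnase4 at 3.19, Creg2 at 2.92, Cd300ld4 at 2.58, Smoc2 at 2.07, Tmem116 at 2.03, D7Ertd143e at 1.55, Appl2 at 1.5, Usp17la at 1.5 and Il1r2 at 1.45. All of these except Appl2, an adaptor protein of endosomes, have a probe at a marked spot, and 7 of these 9 have no other measured probe and so no value without such spots. The remaining measured probe of Tmem116 gave 0.02 and that of Usp17la 0.51. Il1r2, the decoy receptor for interleukin 1, is bright (signals of 809 and 2484) with even spots on both arrays (pixel coefficients of variation of 0.12), although its neighbours differ 4-fold. With marked spots left out, a choice made after the values were seen, the 10 highest included Appl2, Tnfrsf11b (1.32), Alcam (1.27), Emid1 (1.13), Ms4a7 (1.09), Il18 (1.09), Cd68 (1.08), Rgs16 (1.07) and Dhrs3 (1.06). Tnfrsf11b is the decoy receptor osteoprotegerin, Alcam an adhesion molecule, Cd68 a lysosomal glycoprotein of macrophages and Dhrs3 a retinaldehyde reductase.

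Among genes above background on 1 array only, the highest lower bounds were Mapk10 (at least 22.8-fold higher), Olfr298 (at least 18.4-fold), Usp17lb (at least 17.4-fold), Vmn1r12 (at least 13.0-fold) and Cd27 (at least 12.6-fold). In the other direction they were Lyg1 (at least 26.1-fold lower), Aspa (at least 18.5-fold), Kcnmb4os1 (at least 18.4-fold), Fam205c (at least 13.5-fold) and Cyp26b1 (at least 13.5-fold). Each of these 10 bounds rests on 1 probe at a marked spot, so none remains when such spots are left out.

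Marked spots are places on the slide where neighbouring spots differ together. In all, 444 spots (0.749%) differed 4-fold or more between the arrays, 259 of them brighter in the GATA1 siRNA array and 185 in the control siRNA array. Of the 444, 274 had at least 2 such spots among their neighbours, against a median of 2 and a maximum of 8 in 100 shuffles of the spot positions. A marked spot is any spot with at least 2 such neighbours, whatever its own difference, and 1311 spots (2.21%) met this rule. Of the 60 genes at least 2-fold higher 25 have a probe at a marked spot, and of the 125 lower 31 do. With marked spots left out, 35 genes were at least 2-fold higher and 95 lower, and Gata1 stood at -2.22.

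**Figure D2:**
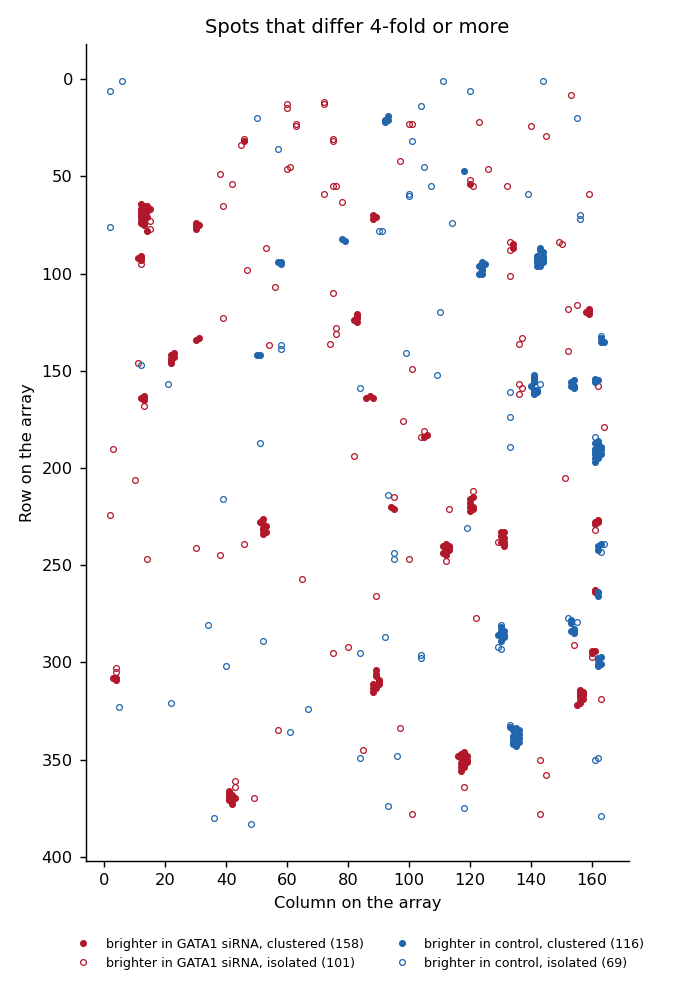
Position on the array, by column and row, of the spots that differ 4-fold or more, coloured by the array on which they are brighter and filled where at least 2 neighbours also differ 4-fold. Filled points, 274 of 444, gather in compact patches rather than spreading over the surface.

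The granule proteases and mediators of mast cells were lower as a list. Their median was -0.07 over 25 measured genes, at percentile 0.03 among 10000 random lists of the same size and signal level, and 15 of the 25 were below 0. The size of this median depends on the scaling, from -0.14 with quantiles to -0.01 with the authors' table. Tpsab1 (-2.11) and Tpsg1 (-1.11), both tryptases, were at least 2-fold lower, and Mcpt4 (-0.88) and Mcpt2 (-0.70), chymase family proteases, came next. Ctsd, a lysosomal protease in the same list, was higher at 0.42. The list of IgE receptor, Kit and other surface receptors had a median of 0.07 over 39 genes (percentile 91.9), with the largest difference at Ptafr, the receptor for platelet-activating factor (0.96). IgE receptor signalling had a median of 0.07 over 32 genes (percentile 87.6), with Sphk1, a sphingosine kinase, at -0.67. Haematopoietic transcription factors had a median of 0.07 over 40 genes (percentile 89.8), and Gata1 was the only member past 2-fold.

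Genes of other blood lineages moved apart. Neutrophil genes had a median of 0.53 (percentile 100), and 24 of 26 were above 0. They included the integrin Itgb2l at 1.01, lactoferrin (Ltf) at 0.79, the glutathione transferase Gstm1 at 0.79 and neutrophilic granule protein (Ngp) at 0.75. Itgb2l was dim, and it turned to -0.10 when probes under background were counted. Macrophage and monocyte genes had a median of 0.27 over 29 genes (percentile 100), with Ms4a7 at 1.09, Cd68 at 1.07 and the transcription factor Maf at 0.85 against the chemokine receptor Cx3cr1 at -0.94. Dendritic cell and MHC class II genes had a median of 0.28 over 18 genes (percentile 100), with H2-Aa at 0.58, Itgax at 0.52 and H2-Eb1 at 0.48 against the chemokine Ccl17 at -0.61. The median of this list was 0.08 with another background correction and 0.12 when probes under background were counted. Progenitor genes had a median of 0.16 over 26 genes (percentile 99.99), and of 0.10 when probes under background were counted. Among them were the transcription factors Sox4 (0.72) and Hoxa7 (0.54), the protein C receptor Procr (0.57) and the surface sialomucin Cd34 (0.46). Hoxa7 was dim, with signals of 17 (control siRNA) and 28 (GATA1 siRNA).

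Eosinophil genes had a median of -0.17 (percentile 0.40; -0.11 with the authors' scaling and -0.26 with brighter probes only), with 9 of 15 below 0. Eosinophil peroxidase (Epx) stood at -0.85, the granule protein Prg3 at -0.71 and the eotaxin receptor Ccr3 at -0.56, whereas Siglecf stood at 0.60. Both Ccr3 (signals of 33 for control siRNA and 25 for GATA1 siRNA) and Siglecf (19 and 32) were dim. Siglecf stood at -0.17 when probes under background were counted. Erythroid genes had a median of -0.04 over 21 genes (percentile 7.6), with Epor 3.0-fold lower and the alpha globin Hba-a2 at 1.0. Megakaryocyte and platelet genes had a median of 0.05 over 25 genes (percentile 74.0), with the platelet glycoprotein Gp1ba at -1.02. Basophil genes had a median of -0.0028 over 22 genes (percentile 8.86), with the activation marker Cd69 at 0.58. Lymphocyte genes had a median of -0.05 over 17 genes (percentile 29.1), with the costimulatory receptor Cd28 at 0.79. Stromal genes had a median of -0.08 over 12 genes (percentile 10.9), with Timp3, an inhibitor of metalloproteinases, at -0.61.

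**Figure D3:**
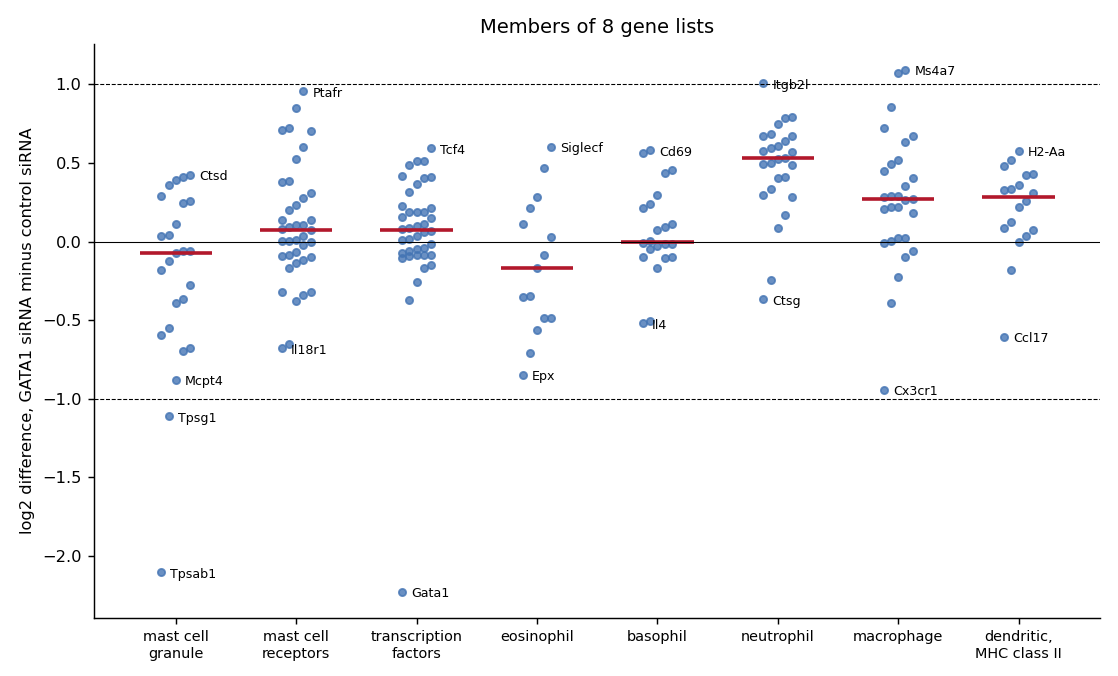
Log2 difference (GATA1 siRNA minus control siRNA) of each measured member of 8 fixed lists, with the list median as a red bar and dashed lines at 2-fold. Neutrophil genes sit mostly above 0 with a median of 0.53, the eosinophil median is -0.17, and Tpsab1 and Gata1 lie below -2.

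Genes of dividing and of responding cells were also higher as lists. Mitotic genes had a median of 0.24 over 34 genes (percentile 100), 29 of them above 0, with the kinases Aurkb at 0.53 and Ttk at 0.46, the anaphase activator Cdc20 at 0.41 and cyclin B2 (Ccnb2) at 0.34. DNA replication genes, by contrast, had a median of 0.08 over 33 genes (percentile 91.0), with the helicase factor Cdc45 at -0.36. Interferon-stimulated genes had a median of 0.20 over 35 genes (percentile 100), 31 of them above 0, with Rtp4 at 0.73, Usp18 at 0.59, the RNA sensor Ifih1 at 0.57 and the GTPase Gbp2 at 0.56. Immediate early genes had a median of 0.18 over 28 genes (percentile 100), 25 of them above 0, with the phosphatases Dusp5 at 0.64 and Dusp2 at 0.58 and the transcription factors Fos at 0.55 and Klf2 at 0.51. The list of p53 targets and apoptosis regulators had a median of 0.20 over 31 genes (percentile 100), 24 of them above 0. Its largest members act in opposite directions: Bcl2l11 (0.84) and Perp (0.83) promote cell death, whereas Bcl2a1d (0.61) is a survival protein and Plk2 (0.52) a p53-responsive kinase. Of the members named here, Aurkb, Ttk, Rtp4, Dusp5 and Plk2 were dim, with control siRNA signals of 32, 23, 19, 36 and 22.

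Lists of general metabolism and housekeeping stayed inside the central 95% of random lists. The median was 0.03 over 27 genes for haem synthesis and iron handling (percentile 54.7), where the haem enzyme Cpox stood at -0.64. It was 0.02 over 26 genes for cytokines and chemokines (percentile 40.3), where Il5, the eosinophil growth factor and a dim gene, stood at -0.82. For eicosanoid synthesis it was 0.05 over 19 genes (percentile 71.7), with the phospholipase Pla2g7 at -0.82. The unfolded protein response gave 0.07 over 28 genes (percentile 77.6), with the disulfide isomerase Pdia4 at 0.45, and heat shock genes 0.03 over 19 genes (percentile 37.1), with the cochaperone Bag3 at -0.36. Cholesterol synthesis gave -0.02 over 25 genes (percentile 8.61), with the regulator Srebf2 at 0.48, and hypoxia and glycolysis 0.09 over 30 genes (percentile 94.9), with the growth factor Vegfa at -0.53. Cytosolic ribosomal proteins gave 0.04 over 58 genes (percentile 18.1), with Rpl5 at 0.15, oxidative phosphorylation 0.06 over 35 genes (percentile 56.8), with Ndufa4 at 0.21, and reference genes 0.09 over 20 genes (percentile 93.7), with Gusb at 0.26. Across the 29 lists, 10 lay outside the central 95%, 8 of them higher and 2 lower. By chance 1.45 would lie outside if the genes of a list varied independently, like genes drawn at random. Genes expressed together can shift together between any 2 cultures, so the excess over 1.45 only describes these 2 arrays.

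**Figure D4:**
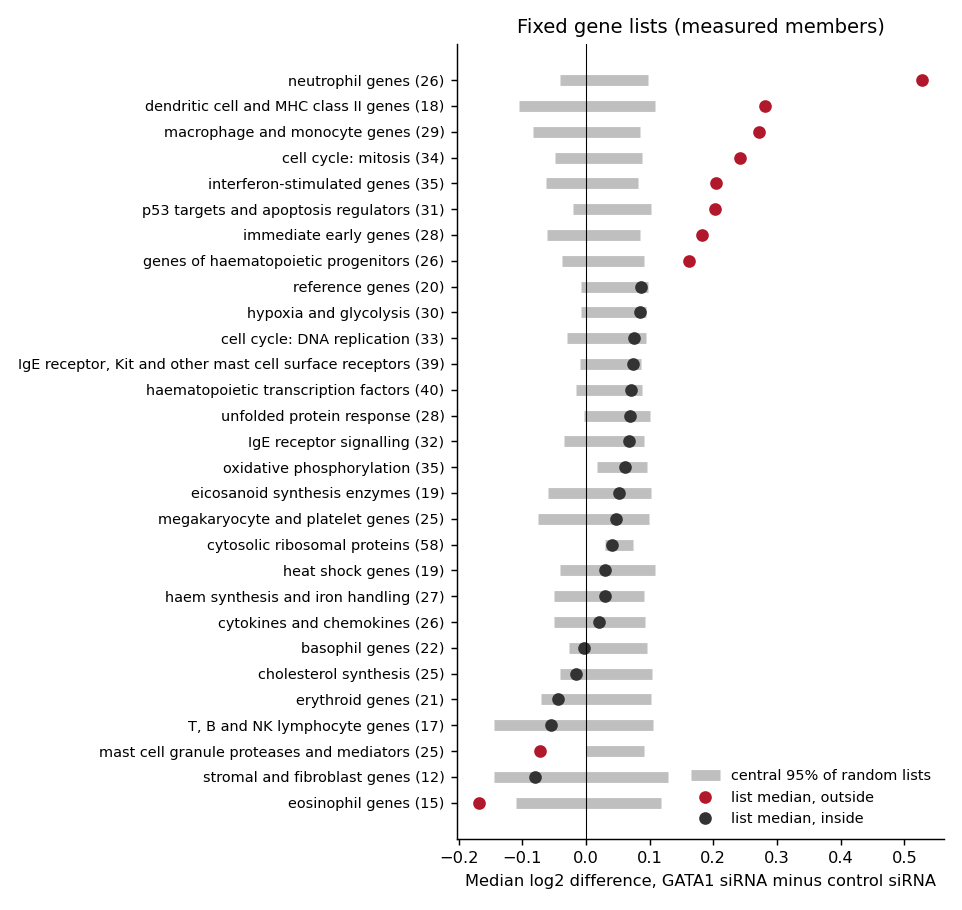
Median log2 difference of each of the 29 fixed lists, with the number of measured members in parentheses, against the central 95% of 10000 random lists matched on signal level (grey bars). Red points, 10 of the 29, lie outside their bar, from eosinophil genes at -0.17 to neutrophil genes at 0.53.

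Within an array, repeated spots of a probe gave close values. Over the 245 measured probes printed 10 times, the median SD of the difference was 0.06, from 0.23 for the dimmest probes to 0.03 for the brightest. Over the 5593 genes with several measured probes, the median SD between probes of a gene was 0.10. Large differences were shared less: of 97 such genes with a probe past 2-fold, all probes had the same sign in 64 and all were past 1.5-fold in 28. These errors cover the array, not the cells or animals.

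In some regions neighbouring probes differed together (regions chosen after their values were seen). The 17 minus-strand noncoding probes on chromosome 2 between 128091693 and 128217944, which include the long noncoding RNA Morrbid (-0.41), were all below 0, with a median of -0.54 and a range of -1.15 to -0.23. Bcl2l11, which lies 107705 bp from them, was higher at both of its probes, by 0.74 and 0.95, and an unnamed minus-strand model between Bcl2l11 and the 17 probes, at 128021751 to 128021810, stood at -0.07. On the plus strand, a noncoding probe that lies between those 17 (at 128127242) stood at -0.03, and the 3 beyond it at 128249465 to 128250301 were below 0, with a median of -0.48. A plus-strand probe of an unnamed model in that same stretch, at 128250240 to 128250299, stood at -0.79. Dgki, a diacylglycerol kinase, was lower at both of its probes (-0.95 and -0.92), and the 7 minus-strand noncoding probes 6558 bp away on chromosome 6, at 36789211 to 36790397, had a median of -1.04. A measured plus-strand noncoding probe that lies among those 7 (at 36789294) stood at -0.07. Beside Gata1, a plus-strand noncoding probe at 7567941 to 7568000 on chromosome X, 31490 bp from the Gata1 probe, stood at -2.06. It is the only measured probe of its locus and lies at an isolated 4-fold spot. Of the features around it, Hdac6 stood at 0.54, Suv39h1 at 0.07, Was at 0.22, Pcsk1n at -0.28 and an unnamed plus-strand model at 7611566 to 7611625 at -0.97, and Glod5 was above background in the GATA1 siRNA array only. None of these probes sits at a marked spot.

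**Figure D5:**
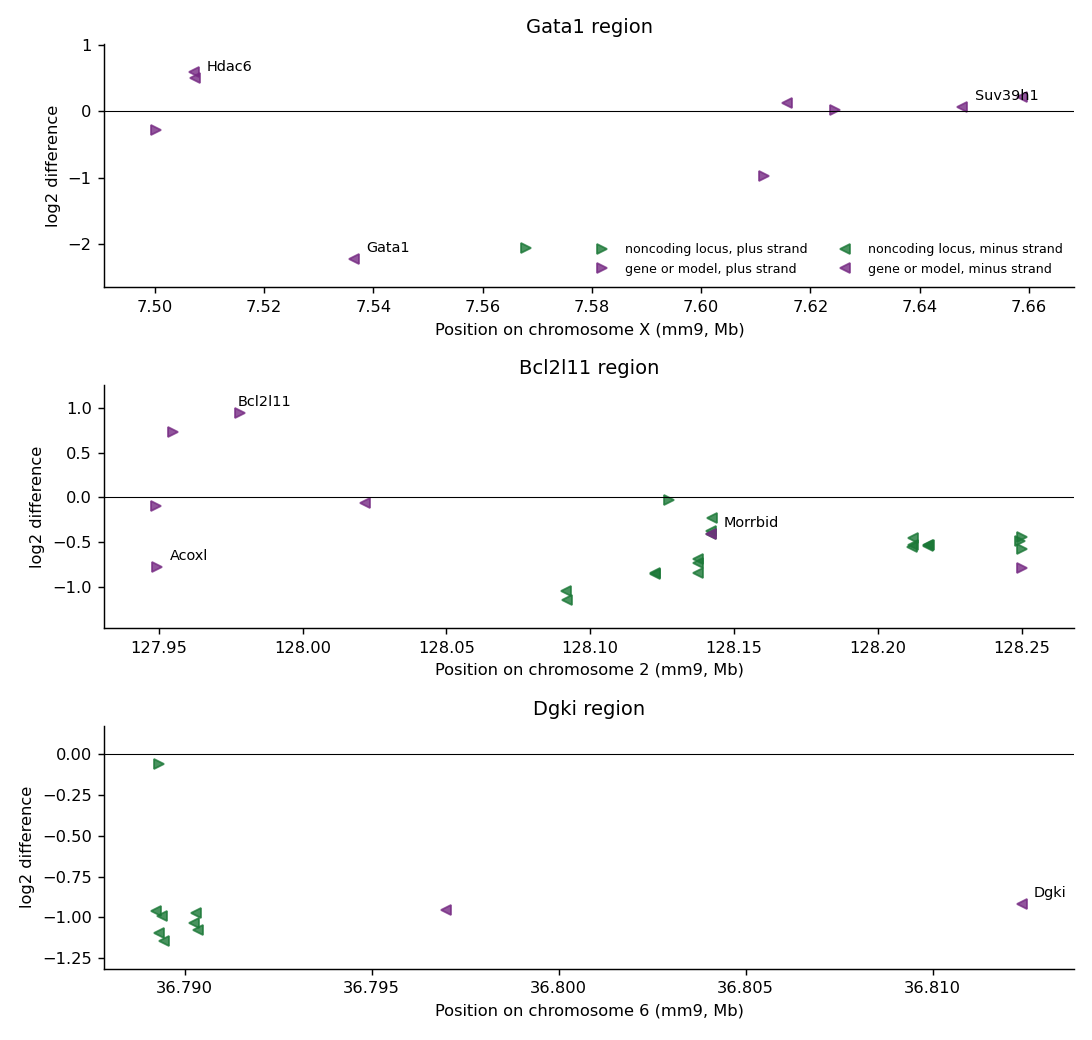
Log2 difference of each measured probe by its position (mm9, in Mb) around Gata1, Bcl2l11 and Dgki, with triangles that point along the strand, green for noncoding loci and purple for genes and models. Beside Dgki the 7 minus-strand noncoding probes have a median of -1.04, and a plus-strand noncoding probe lies at -0.07. The 17 minus-strand probes beyond Bcl2l11 lie between -1.15 and -0.23, and a nearer minus-strand probe of an unnamed model lies at -0.07.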

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

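The alternatives that leave out marked spots and that match random lists on GC content were chosen only after the results were seen. All 10 lists outside the central 95% kept their direction and stayed outside in each of the 11 alternatives that recompute them, with 10 to 13 lists outside (at most 3 more each, among them hypoxia and glycolysis, reference, erythroid, megakaryocyte, DNA replication, cytokine and transcription factor genes), and 10 lay outside with unmatched random lists and with random lists matched on GC content. Gata1 ranged from -2.28 to -2.17 over the same alternatives, the largest moves being quantile scaling (-2.28), loess (-2.28) and the authors' table (-2.17), beyond the error between repeated spots. The counts of genes at least 2-fold higher and of genes at least 2-fold lower moved most: 17 higher and 32 lower with normexp, 739 and 1137 with no filter on dim probes, 11 and 21 with the brighter measured probes only, and 35 higher without marked spots. The cause of the fall with normexp was not tested, and the other moves follow from which probes are counted. A 1.5-fold rule gave 376 higher and 569 lower, and a 3-fold rule 12 and 35. Itgb2l turned to -0.10 with no filter on dim probes, where its other probes count; the cause was not tested further. Of the named genes' values, 876 moved by less than the error between repeated spots, 179 moved by more, and Itgb2l was the 1 gene past 2-fold that reversed. The sign changed in 8 of the 1056 values, of 6 genes: besides Itgb2l, Siglecf (-0.17 with no filter) and Gata2, Kit, Mitf and Ms4a2, which lie near 0. Against the median SD between repeated spots of 0.06, 278 list medians moved by less and 41 by more. That SD is of single spots, so it is a loose measure for a median over many genes. None of the 10 outside lists changed sign, but their medians ranged from -0.14 to -0.01 for granule genes, -0.26 to -0.11 for eosinophil genes, 0.08 to 0.34 for dendritic cell genes and 0.10 to 0.22 for progenitor genes.

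No paired analysis was possible because the groups share only replicate number 1, and leaving out replicates was not possible with 1 array per group. Signal over background limits the dim end: the median difference falls from 0.06 in the brightest of 10 equal groups of genes to -0.12 in the dimmest, and the SD between repeated spots grows from 0.03 to 0.23.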

Other observations

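In this part, the tests of marks on the array surface, of a difference in the RNA, of a lower share of mast cells and of more neutrophils were chosen only after the results were seen, as was the comparison with opposite strands. The tests of GC content and of transcripts that run on past a gene were added once the differences were seen, but set down before their own outcomes were.

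Outside the fixed lists, Ahr, the ligand-activated aryl hydrocarbon receptor, was 2.18-fold lower (-1.12) at both of its probes (-1.19 and -1.06). Globin transcripts went against Epor: Hba-a2 stood at 1.0, its near-identical copy Hba-a1 at 0.69 and the beta globin Hbb-bt at 0.59, whereas Icam4, an erythroid adhesion molecule, stood at -0.81. Among noncoding loci with at least 2 probes, 15 of 1478 were 1.5-fold lower at every probe and 4 were 1.5-fold higher, with a probe at a marked spot in 3 of the 15 and 1 of the 4. Several of the 15 lie close together, as beside Dgki, beyond Bcl2l11 and on chromosome 5. The 15 are therefore not all separate regions. The highest of the 4, a minus-strand locus on chromosome 8 at 82836976 to 82837202, had 3 probes between 1.52 and 1.72. All measured noncoding loci together had a median of -0.10, against 0.03 for named genes, with no match on signal level. Over all measured genes the median difference fell from 0.06 in the brightest group of genes to -0.12 in the dimmest. Whether noncoding loci differ from named genes of the same level was not tested.

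Single spots that differ 4-fold or more account for most of the highest differences between the arrays. Marks on the array surface are a candidate explanation for the clustered ones, since 274 of the 444 spots had at least 2 such neighbours, against 8 at most in shuffled positions. A difference in the RNA at most of these clustered spots is argued against where the gene has another probe, at an unmarked spot and measured on both arrays. Of 144 such probes, 1 differed 2-fold in the same direction. For the isolated 4-fold spots 3 of 67 such probes did so, which argues against a difference in the RNA for most of those with such a probe. Genes whose other probes were above background on 1 array only were not covered by either count. Gata1, Tpsab1 and Hsd11b2 lie at isolated 4-fold spots and have no other measured probe, so for these a difference in the RNA stays open. Brightness varied within clustered 4-fold spots (median pixel coefficient of variation 0.42) about as much as within isolated 4-fold spots (0.44), against 0.30 within other spots as bright as the clustered ones, so it does not tell clustered from isolated spots, and it was lower at Gata1 (0.16 control siRNA, 0.19 GATA1 siRNA), Tpsab1 (0.13, 0.21) and, on the control siRNA array, Hsd11b2 (0.22, 0.31), with no match on their brightness.

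Neutrophil genes were higher as a list, and the level and GC content of their probes are argued against, since the list stayed at percentile 100 among named genes matched on both. A lower share of mast cells alone would raise eosinophil genes too. The neutrophil median exceeded the eosinophil median by 0.79, against a spread of 0.38 among members, with 1 shared gene left out. GATA1 is itself a factor of eosinophils, so the siRNA could lower those genes whatever the share, and this comparison cannot decide. Macrophage (0.27), dendritic cell (0.28) and progenitor (0.16) medians were also higher than in random lists, the direction of a lower share. Lymphocyte (-0.05), stromal (-0.08), erythroid (-0.04), basophil (-0.0028) and megakaryocyte (0.05) medians lay inside the range of random lists. A lower share thus stays open. More neutrophils among the cultured cells stay possible but untested on genes outside the neutrophil list. Of the 26 measured genes in that list, 2 were below 0, Csf3r (-0.24, at a marked spot) and Ctsg (-0.37). Its members Cd177, Mmp9 and Retnlg were not well above background on either array. Of the abundant transcripts, S100a9 stood at 0.60 and S100a8 at 0.61. Csf3r and Ctsg were bright in the control siRNA array (log2 8.05 and 6.69), Ctsg and Cebpe stand in another list too, and the labels name no sort that would remove such cells. Whether the GATA1 siRNA itself brought the pattern about cannot be told apart from a difference between the pooled samples, with 1 array per group.

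Of the tryptases and chymases, 7 chosen after their values were seen were lower, with Tpsab1, Tpsg1, Mcpt4, Mcpt2 (-0.70), Mcpt1 (-0.68), Cma2 (-0.60) and Tpsb2 (-0.55), whereas Cma1, the brightest chymase, differed by only -0.12, and the related proteases Mcpt8 and Prss34, counted here among basophil genes, stood at 0.29 and 0.24. A lower share of mast cells as the only cause is argued against, because Cpa3, Kit, Fcer1a, Ms4a2, Hdc, Tph1 and Srgn lay between -0.17 and 0.04 (SD 0.07), above Tpsb2 by more than their spread. That set was chosen after the results were seen and leaves out Cma1 and Il1rl1. Il1rl1, at -0.32, lay below the set but above Tpsb2, so a small part of the pattern could still come from a lower share. Marks that span several spots are argued against as well, since 0 of the 8 probes of these 7 genes sit at marked spots. That rule cannot detect a defect of a lone spot. Tpsab1 lies at an isolated 4-fold spot, so for it a defect stays open. Lower transcription of these proteases with less GATA1 may explain the pattern and was not tested, and a difference between the pooled samples stays open.

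The low noncoding probes beside Dgki raised the hypothesis that transcripts run on past the ends of genes, so that noncoding loci follow their neighbours. Across 378 loci within 20 kb of a named gene on the same strand, Spearman's rho between the differences was 0.16 (bootstrap interval 0.05 to 0.26), against -0.03 for 303 loci over 100 kb away. On the opposite strand within 20 kb it was 0.14 (233 loci, -0.0020 to 0.27), and from 20 to 100 kb it was 0.12 (523 loci). Pearson's r was 0.30 (0.15 to 0.44) on the same strand, 0.23 without the 2 loci beside Dgki, and 0.15 (-0.02 to 0.33) on the opposite strand. The intervals overlap, so transcripts that run on and nearness alone cannot be told apart here, and they cover the choice of loci only, which are not independent replicates.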
